A study of Arabidopsis thaliana with 9 samples.

How the data were processed

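RNA from 3 Arabidopsis thaliana lines, iae1, iae2 and B1798, was measured on 9 Affymetrix ATH1 arrays, with 3 arrays per line. Per the labels, all lines were in the Ler ecotype, total RNA was extracted with phenol and SDS, and cRNA was made from cDNA primed with oligo-dT and labelled with biotin. The values used were the deposited intensity signals, on a linear scale, of 22810 probe sets per array. The algorithm that summarised the probes into probe sets was not given in the sources used here. The values ranged from 0 to 8093, and the mean left after trimming 2 percent of the probe sets at each end was 100 on each of the 9 arrays, so a common scaling had been applied before deposition. Array medians lay between 35.9 and 38.5.

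The 64 AFFX control probe sets were left out of all tests. A probe set was tested when its value was at or above the 40th percentile of its own array in at least 3 of the 9 arrays, which kept 14404 of the other 22746. Values were taken as log2(value + 16) with no further normalization, so each fold change refers to that scale and understates the change of dim probe sets. Linear models with a mean per line were fitted to all 9 arrays with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance. Contrasts were tested on both sides, and the Benjamini-Hochberg method was applied over all tested probe sets of a contrast. A probe set was called at an adjusted p below 0.05, and every adjusted p given for a gene comes from these limma fits. A moderated F test gave the calls over any line. The number of arrays limits the precision of every value.

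B1798 was taken as the reference because it is the line without an iae name. No label calls it a control. The labels number the arrays of a line as replicates and do not say that these came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The tests, filter, lists, rule for named genes and most of the other settings tried were written before the data were examined.

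The probe annotation named 13513 probe sets with 1 gene and 503 with several, and 8730 were unnamed here. Among the tested probe sets these numbers were 7853, 292 and 6259. Locus identifiers and gene order were taken from a gene table of assembly TAIR10.1, which held a locus for all but 77 of the 13513 probe sets with 1 gene. The tested ones gave 7752 genes. No coordinates are reported because the sources name no genome build. Where a gene had several probe sets, the brightest over all arrays stood for it in the gene lists. Probe sets of the kinds that can detect several transcripts are marked in the text as able to cross-hybridise.

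Named genes followed a rule. In each of the 3 contrasts it took the 8 largest rises and the 8 largest falls among called probe sets with 1 gene whose 3 arrays of each line did not overlap. It also took 6 genes called in the same direction in iae1 and iae2 by the larger of their smaller changes, up to 3 members of each gene list by adjusted p, and any called list member. Genes outside the rule are identified as such where they appear.

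Calls shared by iae1 and iae2 were set against 100 simulations of unchanged groups compared with the same B1798 arrays, and against the overlap of independent lists. Neighbouring lost genes were pairs of genes next to each other in the order of tested genes that were both called lower by at least 2-fold. Their number was tested on one side with 100000 permutations. The 22 gene lists held 452 loci, of which 46 were tested. Of the lists, 10 had at least 3 tested members and entered camera, a competitive gene set test in limma, with a preset correlation of 0.01 and again with an estimated correlation. A further 7 lists had 1 or 2 tested members. The 5 lists with no tested member were chloroplast protein import, SR proteins and splicing, dark and sugar starvation, seed storage and embryo markers, and flowering markers. Lists of transposable elements and of cytosolic ribosomal proteins were planned by description text, which the tables used do not carry, and were not analysed here.

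Array quality was read from the 3'/5' signal ratios of the GAPDH and actin control probe sets, the 25S rRNA probe set, the scanner background per the labels, and the percent of values under 16. These were compared with exact permutation tests, whose smallest possible p is 0.1 for 3 arrays against 3. The alternatives changed the pseudocount, the floor, the normalization, the filter, the variance model, array weights, the lines in the fit, the threshold and the probe sets per gene, added the replicate number as a block, and left out each array in turn. On simulated data for iae1 against B1798 with 14404 probe sets, 200 of them changed, the fit recovered 69 of 100 changes of log2 0.5 and 100 of 100 changes of log2 1, with 11 false calls. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.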

Results

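Transcript levels were compared among the Arabidopsis lines iae1, iae2 and B1798, with 3 arrays each. The iae lines are known from work on mutations that raise excision of the maize transposon Ac in Arabidopsis, and the series title states the aim of working out what underlies their phenotypes genetically. The tissue was crown, hypocotyl, cotyledons and apical meristem bud of plants given sucrose, and the series text gives a pool of 30 plants without saying for which unit. Signals of the 22810 probe sets were scaled to the same trimmed mean of 100 on all arrays. Arrays of a line correlated with each other at a mean r of 0.985 for B1798, 0.988 for iae1 and 0.989 for iae2 across probe sets, which are not independent replicates. Between lines the mean r was 0.978 for B1798 with iae1, 0.967 for B1798 with iae2 and 0.966 for iae1 with iae2.

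Signs of RNA quality were read on each array. The GAPDH 3'/5' signal ratio was 2.73 ± 0.42 (SD, n = 3) in B1798, 2.42 ± 0.0875 in iae1 and 1.86 ± 0.126 in iae2. The exact permutation p against B1798 was 0.4 for iae1 and 0.1 for iae2, the latter being the smallest that 3 arrays against 3 allow. The actin 3'/5' ratio was 2.64 ± 0.175 in B1798, 2.30 ± 0.154 in iae1 (exact p = 0.2) and 1.99 ± 0.271 in iae2 (exact p = 0.1). The signal of the 25S rRNA probe set was 3619 ± 416 in B1798, 4847 ± 384 in iae1 (exact p = 0.1) and 2887 ± 1058 in iae2 (exact p = 0.4), where replicate 2 had 1666. Scanner background was 57.3 ± 2.19 in B1798, 58.3 ± 8.24 in iae1, with 67.81 on replicate 3, and 61.7 ± 1.76 in iae2. The share of values under 16 was 31% in B1798, 29.8% in iae1 and 30.1% in iae2.

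In iae1 against B1798, AT2G35750 rose from a signal of 90.8 ± 21.1 to 1179 ± 67.6 (SD, n = 3), a log2 fold change of 3.50 ± 0.11 (SE, adjusted p = 5.21e-11). The pseudogene AT5G28110, read by a probe set that can cross-hybridise, was near 0 in B1798 and iae2 (1.3 ± 0.2 and 1.73 ± 1.23) and reached 200.1 ± 34.3 in iae1 (log2 fold change 3.63, adjusted p = 3.56e-10). ICL, the isocitrate lyase of the glyoxylate cycle, rose from 14.4 ± 9.92 to 63.9 ± 7.25 (1.44 ± 0.18, adjusted p = 0.000114), and AT3G13610, a feruloyl-CoA hydroxylase of scopoletin synthesis, from 26.4 ± 15.4 to 116 ± 18.5 (1.68 ± 0.19, adjusted p = 4.35e-05). Among the falls, the beta-glucosidase gene BGLU28 went from 209.7 ± 40.4 to 55.0 ± 4.31 (log2 fold change -1.65 ± 0.12, adjusted p = 6.7e-07). AT5G03350, which encodes a legume-lectin domain protein, went from 171 ± 8.8 to 44.8 ± 10.3 (-1.64 ± 0.14, adjusted p = 2.81e-06).

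The other leading rises in iae1 were the pseudogene AT2G26630 (log2 fold change 1.81), AT5G03090 (1.57), AT5G66985 (1.51) and the defensin gene PDF1.2b (1.42, from a probe set that can cross-hybridise). Their adjusted p-values ran from 1e-06 for AT2G26630 to 0.000137 for PDF1.2b. The other leading falls were AT5G55450, of the lipid transfer protein family (-1.48), AT4G17470 (-1.45), the late embryogenesis abundant gene M10 (-1.22), AT1G64360 (-1.08), the TIR-NBS type gene AT3G04210 (-1.08) and AT1G16020 (-0.98), with adjusted p-values between 2.38e-06 for AT5G55450 and 0.00707 for AT3G04210. In all, 1039 of 14404 probe sets were called, 547 higher and 492 lower, or 512 and 519 with array medians set equal, so the balance of directions depends on the scaling. At least 2-fold changes numbered 67 (46 higher, 21 lower), a count that depends on the pseudocount: 123 with log2(value + 4), 119 with values below 16 set to 16 and 17 with log2(value + 64). The named single-gene probe sets among them covered 494 of 7752 genes. The arrays of iae1 and B1798 did not overlap for 24.7% of the tested probe sets, where chance gives 10%. The count was 615 without B1798 replicate 2 and 650 without iae1 replicate 3, and 645 with the GAPDH 3'/5' ratio as a covariate, a fit added after the counts were seen, where the median size of the log2 fold changes of the 1039 went from 0.45 to 0.44 and the median standard error from 0.096 to 0.109.

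**Figure D1:**
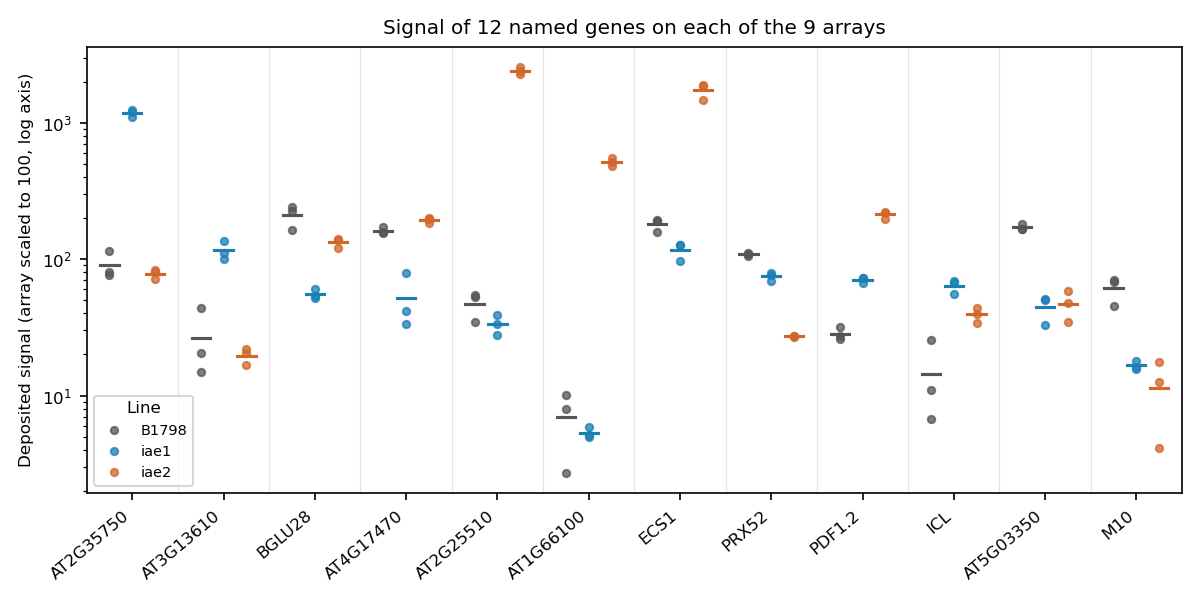
Signal of named genes on each array, on a log axis, for B1798, iae1 and iae2; points are arrays and bars are line means (n = 3). AT2G35750 stands near 1179 in iae1 alone, and AT2G25510, AT1G66100 and ECS1 stand highest in iae2.

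In iae2 against B1798, AT2G25510 rose from 47.2 ± 11.1 to 2397 ± 139 (SD, n = 3), a log2 fold change of 5.27 ± 0.12 (SE, adjusted p = 2.57e-13). AT1G66100, of the thionin family of antimicrobial peptides, rose from 6.90 ± 3.8 to 519 ± 35.2 (4.56 ± 0.13, adjusted p = 2.2e-12). ECS1, which encodes a cell-wall protein described as expressed in some ecotypes and not in others, rose from 180.5 ± 19.3 to 1731 ± 235 (3.15 ± 0.11, adjusted p = 6.06e-11). The defensin gene PDF1.2 rose from 28.3 ± 3.25 to 213 ± 13.6 (2.37 ± 0.10, adjusted p = 1.61e-10). Among the falls, the class III peroxidase gene PRX52 went from 108.5 ± 2.34 to 27.1 ± 0.379 (-1.53 ± 0.09, adjusted p = 2.04e-08), and BGLU46, a monolignol beta-glucosidase gene, from 134 ± 7.73 to 41.1 ± 5.81 (-1.40 ± 0.10, adjusted p = 7.49e-08).

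The other leading rises in iae2 were AT5G23830, with an MD-2-related lipid recognition domain (log2 fold change 3.40), the TRAF-like gene ZW9 (3.16), AT2G01090, a hinge protein gene of the mitochondrial cytochrome bc1 complex (2.95), and AT5G45500 (2.38). Their adjusted p-values ran from 3.03e-10 for AT2G01090 to 9.55e-08 for AT5G23830. The other leading falls were AT5G03350 (-1.59), M10 (-1.51), the peroxidase gene Prx37 (-1.50), AT3G18250 (-1.41), AT3G48640 (-1.37) and the pectin methylesterase gene ATPMEPCRD (-1.30), with adjusted p-values between 2.1e-07 for AT3G18250 and 2.81e-05 for M10. In all, 2558 probe sets were called, 1407 higher and 1151 lower, or 1286 and 1308 with array medians set equal. Of them 183 changed by at least 2-fold (132 higher, 51 lower), against 310 with log2(value + 4), 318 with values below 16 set to 16 and 69 with log2(value + 64). They covered 1298 of 7752 genes, and the arrays of the lines did not overlap for 33.3% of tested probe sets against 10% by chance. The GAPDH and actin 3'/5' ratios were lower on every iae2 array than on every B1798 array. With the GAPDH ratio as a covariate, added after the counts were seen, 526 probe sets were called, the median standard error of the 2558 rising from 0.0991 to 0.185 while the median size of their log2 fold changes went from 0.45 to 0.44.

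The question of a deletion was put to the order of genes, since the loss of a chromosome piece would lower neighbours together. In iae1, 7 genes were called lower by at least 2-fold, and 0 pairs of them were neighbours among the 7686 genes in order (expected 0.00545, one-sided permutation p = 1). In iae2, 23 genes were, again with 0 neighbouring pairs (expected 0.0657, one-sided permutation p = 1). In all, 21 probe sets in iae1 and 51 in iae2 were called lower by at least 2-fold. Those without a single located gene, the largest unnamed falls among them, had no place in the order. With so few genes in it, the test could miss a small deletion. With no fold minimum there were 9 pairs among 233 genes in iae1 (expected 7.03, permutation p = 0.272) and 53 among 577 in iae2 (expected 43.2, permutation p = 0.0666). Of the probe sets under the filter level in B1798 and at least 4 times that level in an iae line, 1 was found for iae1 (AT5G28110) and 4 for iae2 (AT1G66100, AT5G23830, AT2G01090 and an unnamed probe set). Of those with the reverse pattern 0 were found in either line.

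Few photosynthesis genes were tested, and their calls are no sign of more or fewer changes than elsewhere. Over all genes, 494 of 7752 were called in iae1 and 1298 of 7752 in iae2. Of 7 tested photosystem and light-harvesting genes, 0 passed in iae1, and LHCB4.2, the CP29 antenna protein gene, rose in iae2 from 1773 ± 184 to 2679 ± 182 (log2 fold change 0.59, adjusted p = 0.000188). Adjusted over the list alone the numbers were 0 and 2, with ATPC1 the addition. Camera gave an adjusted p = 0.499 for the list in iae1 and an adjusted p = 0.668 in iae2, where the list's median log2 fold change was -0.08 while camera's direction was up. ATPC1 and PSBY had log2 fold changes of 0.22 and 0.19 in iae2 and did not pass (adjusted p = 0.0504 and 0.183). Of 3 Calvin cycle genes, SBPASE rose in iae1 (0.31, adjusted p = 0.0458) and PRK in iae2 (0.28, adjusted p = 0.0219), 1 in each also adjusted over the list alone, while RCA did not pass (0.12 and 0.01). For the Calvin cycle list camera gave an adjusted p = 0.238 in iae1 and an adjusted p = 0.411 in iae2. The SBPASE call was lost when any array other than iae2 replicates 1 and 2 was left out (adjusted p up to 0.145) and with equal array medians. The PRK call was lost without iae2 replicate 2 or 3 or B1798 replicate 1 or 3 (up to 0.0825).

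In the jasmonate and wounding list, PDF1.2 and PDF1.2b, plant defensin genes, rose in iae1 (log2 fold change 0.97 and 1.42) and in iae2 (2.37 and 1.75). THI2.1, a thionin gene, fell in iae2 from 384 ± 14 to 176 ± 12.3 (-1.06, adjusted p = 1.39e-07) and in iae1 to 316 ± 13.9 (-0.27, adjusted p = 0.046). All 3 tested members passed in each line, also adjusted over the list alone, yet in both directions, and camera gave an adjusted p = 0.0821 in iae1 (adjusted p = 0.254 with an estimated correlation) and an adjusted p = 0.245 in iae2. The THI2.1 call in iae1 was lost when any array other than iae2 replicate 1 was left out (adjusted p up to 0.153). Of 4 auxin response genes, WES1, an auxin-conjugating enzyme gene, fell in iae2 (-0.36, adjusted p = 0.00367), and GH3.3 (-0.19 in iae1, -0.21 in iae2) and IAA29 (-0.17 and -0.15) did not pass. The auxin counts adjusted over the list alone were 0 in iae1 and 1 in iae2, with a camera adjusted p = 0.336 and adjusted p = 0.245. EIN3, a transcription factor of ethylene signalling and the tested member of the ethylene list, fell in iae2 (-0.25, adjusted p = 0.0412), a call lost without any array of iae2 or B1798 (up to 0.113). SAG101, the tested member of the salicylate list, had log2 fold changes of 0.00 in iae1 and -0.10 in iae2 and did not pass (adjusted p = 0.993 and 0.629).

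In the list of cold, drought and abscisic acid, COR15A and COR15B, genes of chloroplast proteins induced by cold, rose in iae2 (log2 fold change 0.74, adjusted p = 0.00218, and 0.76, adjusted p = 0.00028), the dehydrin gene COR47 fell in iae2 (-0.49, adjusted p = 0.000766), and COR15B fell in iae1 (-0.44, adjusted p = 0.0342). Of 4 tested members 1 passed in iae1 and 3 in iae2, or 1 and 4 adjusted over the list alone (LTI30, outside the rule for named genes, added with 0.28 in iae2, adjusted p = 0.135 over all), with a camera adjusted p = 0.238 and adjusted p = 0.245. The COR15B call in iae1 was lost without iae1 replicate 1 or 2 or B1798 replicate 2 or 3 (adjusted p up to 0.136). Of 4 heat shock genes 0 passed in either line, with 2 in iae1 (AT5G37670 and AT5G48570) and 0 in iae2 adjusted over the list alone, and camera gave an adjusted p = 0.0821 in iae1 (adjusted p = 0.254 with an estimated correlation) and an adjusted p = 0.663 in iae2. AT5G37670 had log2 fold changes of -0.34 and -0.08 in iae1 and iae2, AT5G48570 of -0.33 and 0.15, and AT1G53540 of 0.01 and -0.40. With quantile normalization the jasmonate and the heat shock lists passed in iae1 (adjusted p = 0.0497 for each, or 0.202 with an estimated correlation). Of 3 flavonoid genes, the anthocyanin gene DFR rose in iae2 (0.59, adjusted p = 0.00518), while UF3GT (0.17 and 0.33) and UGT78D2 (-0.24 and -0.15) did not pass. The flavonoid counts were 0 in iae1 and 1 in iae2, also adjusted over the list alone, with a camera adjusted p = 0.776 and adjusted p = 0.314.

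Of 4 glucosinolate genes, AOP3, which modifies the side chain, fell in iae2 from 151 ± 23.8 to 61.0 ± 11.2 (log2 fold change -1.12, adjusted p = 1.34e-05). BCAT4, of methionine chain elongation, fell in iae2 (-0.67, adjusted p = 0.000123) and rose in iae1 (0.38, adjusted p = 0.0221), the latter call being lost without iae1 replicate 2 or 3 or B1798 replicate 2 or 3 (adjusted p up to 0.0896). AT2G31790 did not pass (0.03 and 0.29). The counts adjusted over the list alone were 1 in iae1 and 2 in iae2. For the glucosinolate list camera gave an adjusted p = 0.336 in iae1 and an adjusted p = 0.245 in iae2, or 0.406 with an estimated correlation. Without B1798 replicate 3 the list passed in iae2 (adjusted p = 0.0468), but not with an estimated correlation (adjusted p = 0.308). Of 3 root markers, the beta-glucosidase gene PYK10 fell in iae2 (-0.33, adjusted p = 0.00898), a call not made with quantile normalization (adjusted p = 0.165), and the peroxidase gene AT5G17820 rose in iae1 (0.51, adjusted p = 0.0202), a call lost without iae1 replicate 1 or 2 or B1798 replicate 2 or 3 (up to 0.0896). EXPA7 did not pass (0.17 and 0.31), the counts adjusted over the list alone were 1 in iae1 and 3 in iae2, and camera gave an adjusted p = 0.336 and an adjusted p = 0.668.

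Of 2 seed oil mobilisation genes, ICL rose in iae1 (log2 fold change 1.44) and iae2 (0.91, adjusted p = 0.00214), while the oil body lipase gene SDP1 fell in iae2 (-0.41, adjusted p = 0.0158), a call lost without iae2 replicate 3 or B1798 replicate 2 (up to 0.0815). Adjusted over the list alone, 1 passed in iae1 and 2 in iae2. In the lists nearest to transposon excision no change passed, but few of their loci were tested. These were 1 of 36 loci for DNA methylation and silencing and 3 of 39 for DNA repair. That is too few to say whether these pathways changed. The DNA methylation list was read by DME alone (-0.06 in iae1, adjusted p = 0.862, and 0.04 in iae2, adjusted p = 0.876). The 3 DNA repair genes ATLIG4 (0.04 and -0.22), TOP3A (0.27 and 0.04) and RAD4 (-0.09 and -0.14) had 0 calls, also adjusted over the list alone, with a camera adjusted p = 0.776 in iae1 and adjusted p = 0.453 in iae2. At an unadjusted p below 0.05 limma gave 3070 probe sets in iae1 and 4352 in iae2 over all those tested. PRL, of the cell cycle list (-0.01 and 0.26), the clock gene GI (0.03 and -0.10) and the meristem marker LAS (0.10 and 0.06) did not pass either, also adjusted over the list alone. Of the 10 lists in camera, 0 passed at an adjusted p of 0.05 in any of the 3 contrasts. The lower GAPDH and actin 3'/5' ratios of iae2 stand beside each of these groups. Beside the iae1 values stands the 25S rRNA signal, which was higher on every iae1 array than on every array of the other lines. With the GAPDH ratio as a covariate, added later, 9 of these iae2 calls were lost, with standard errors of 0.0756 to 0.179 rising to 0.127 to 0.359. Larger than before were the log2 fold changes of PRK (0.28 to 0.48), SDP1 (-0.41 to -0.54), DFR (0.59 to 0.69) and COR15A (0.74 to 0.85). Smaller were those of ICL (0.91 to 0.82), WES1 (-0.36 to -0.25), EIN3 (-0.25 to -0.16), COR47 (-0.49 to -0.23) and PYK10 (-0.33 to -0.16). In iae1 the calls of SBPASE (0.31 to 0.34), THI2.1 (-0.27 to -0.28), COR15B (-0.44 to -0.36), BCAT4 (0.38 to 0.28) and AT5G17820 (0.51 to 0.43) were lost, with standard errors of 0.077 to 0.123 rising to 0.0905 to 0.141.

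**Figure D2:**
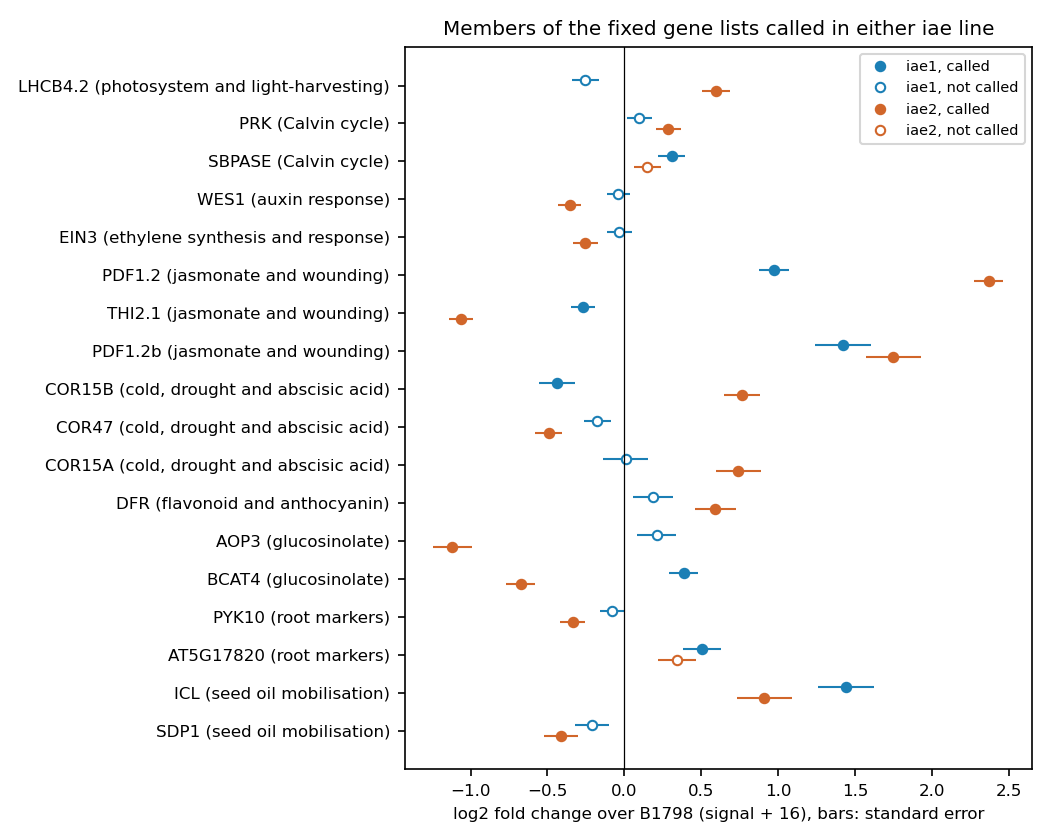
Log2 fold changes over B1798, on the log2(signal + 16) scale, of the members of the gene lists called in iae1 or iae2; points are estimates and bars are standard errors (n = 3 per line), with open points for values not called. PDF1.2, PDF1.2b and ICL lie above 0 in both lines, and COR15B and BCAT4 lie on opposite sides of 0.

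More probe sets were called between the iae lines than between iae1 and B1798. AT2G35750 and AT5G28110 were higher in iae1 than in iae2 (log2 difference 3.67 ± 0.11 SE, adjusted p = 6.44e-12, and 3.60 ± 0.14, adjusted p = 9.09e-11), as were BGLU46 (1.68, adjusted p = 8.68e-09), the jacalin lectin gene AT5G35940 (1.69, adjusted p = 1.33e-08), with 258 ± 28.3 in iae1, 97.4 ± 8.43 in B1798 and 69.1 ± 7.05 in iae2, and the defensin-like gene AT4G22212 (1.67, adjusted p = 7.61e-09), with 1011 ± 117, 412 ± 44.4 and 304 ± 11.6. AT2G25510 (-5.62, adjusted p = 9.77e-14), AT1G66100 (-4.65, adjusted p = 1.64e-12) and ECS1 (-3.71, adjusted p = 6.44e-12) were lower in iae1. Other leading differences were AT3G13610 (1.88), AT2G26630 (1.76) and AT5G03090 (1.68), higher in iae1, and ZW9 (-3.16), AT5G23830 (-3.01), AT2G01090 (-2.78), AT5G45500 (-2.40) and the methyltransferase gene AT5G37990 (-2.27), lower in iae1, with adjusted p-values between 6.07e-10 for AT2G01090 and 4.27e-06 for AT3G13610. Limma called 2825 probe sets, 1360 higher and 1465 lower in iae1, or 1442 and 1382 with array medians set equal, covering 1429 genes. Of the 2825, 199 changed by at least 2-fold (70 higher, 129 lower), against 319 with log2(value + 4), 317 with values below 16 set to 16 and 80 with log2(value + 64). The arrays did not overlap for 35.8% of tested probe sets against 10% by chance. With the GAPDH ratio as a covariate, added later, 1470 probe sets were called, the median standard error rising from 0.0985 to 0.14 with the median size of the log2 differences at 0.44 and 0.45.

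Between the iae lines the glucosinolate genes AOP3 (log2 difference 1.33, adjusted p = 2.07e-06) and BCAT4 (1.06, adjusted p = 1.14e-06) were higher in iae1, and LHCB4.2 (-0.85, adjusted p = 5.39e-06), COR15B (-1.20, adjusted p = 3.02e-06), COR15A (-0.73, adjusted p = 0.00225) and PDF1.2 (-1.40, adjusted p = 5.81e-08) were lower. Camera gave an adjusted p = 0.0922 for the glucosinolate list and for the cold list, and adjusted p-values from 0.46 to 0.823 for the other 8 lists. THI2.1 (0.79, adjusted p = 2.75e-06) and WES1 (0.32, adjusted p = 0.0078) were higher in iae1. ICL was higher in iae1 (0.53, adjusted p = 0.0494), a call lost when any array other than B1798 replicates 2 and 3 was left out (up to 0.16). DFR was lower (-0.41, adjusted p = 0.0415), a call lost without iae1 replicate 2 or 3 or iae2 replicate 2 or 3 (up to 0.161), and PYK10 was higher (0.25, adjusted p = 0.0385), a call lost without any iae1 array or iae2 replicate 1 or 2 (up to 0.137) and with quantile normalization. COR47 was higher (0.32, adjusted p = 0.016) and the heat shock list's AT5G48570 lower (-0.49, adjusted p = 0.0123), calls lost without iae1 replicate 1 or iae2 replicate 1 or 2 (up to 0.0729 and 0.059). With the GAPDH ratio as a covariate 6 of these calls were lost, namely ICL (0.53 to 0.58), DFR (-0.41 to -0.47), AT5G48570 (-0.49 to -0.40), WES1 (0.32 to 0.25), COR47 (0.32 to 0.15) and PYK10 (0.25 to 0.14), with standard errors of 0.0756 to 0.179 rising to 0.096 to 0.27.

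Genes called in the same direction in iae1 and iae2 against B1798 included AT5G03350 (log2 fold change -1.64 in iae1 and -1.59 in iae2), PDF1.2b (1.42 and 1.75), AT5G55450 (-1.48 and -1.28) and M10 (-1.22 and -1.51). RALFL27, of the RALF family of signal peptides, rose from 2.30 ± 1.15 to 26.4 ± 5.72 and 29.8 ± 3.0 (1.2 and 1.32), and the peroxidase gene AT4G26010 from 25.8 ± 6.79 to 74.6 ± 6.72 and 89.7 ± 9.97 (1.12 and 1.34). In total 239 probe sets were called higher and 180 lower in both lines, where independent lists of the same lengths would share 53.4 and 39.3. Simulated unchanged groups against the same B1798 arrays gave means of 0.01 and 0, but such groups yield almost no calls, so these numbers are no measure for lists of this length. Of these 419, 114 also differed between iae1 and iae2. The covariance of the log2 fold changes was 0.0238 against a simulated mean of 0.0073, a difference of 0.0165, and their correlation was 0.331 against a simulated 0.499. With the 3 B1798 arrays divided between the contrasts, 1 and 2, in each of 6 ways, a choice made after the counts were seen, 110 to 184 probe sets were shared. Independent lists of those lengths would share 11.7 to 20.6 higher and 7.85 to 13.2 lower, and the covariance was 0.0122 to 0.0169. Each division leaves fewer arrays per contrast, and part of the excess among the 419 may come from the shared controls. The shared count was 248 without B1798 replicate 2, 269 without iae1 replicate 3 and 122 with the GAPDH ratio as a covariate, and the RALFL27 call in iae1 was not made with values below 16 set to 16 (adjusted p = 0.0557).

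**Figure D3:**
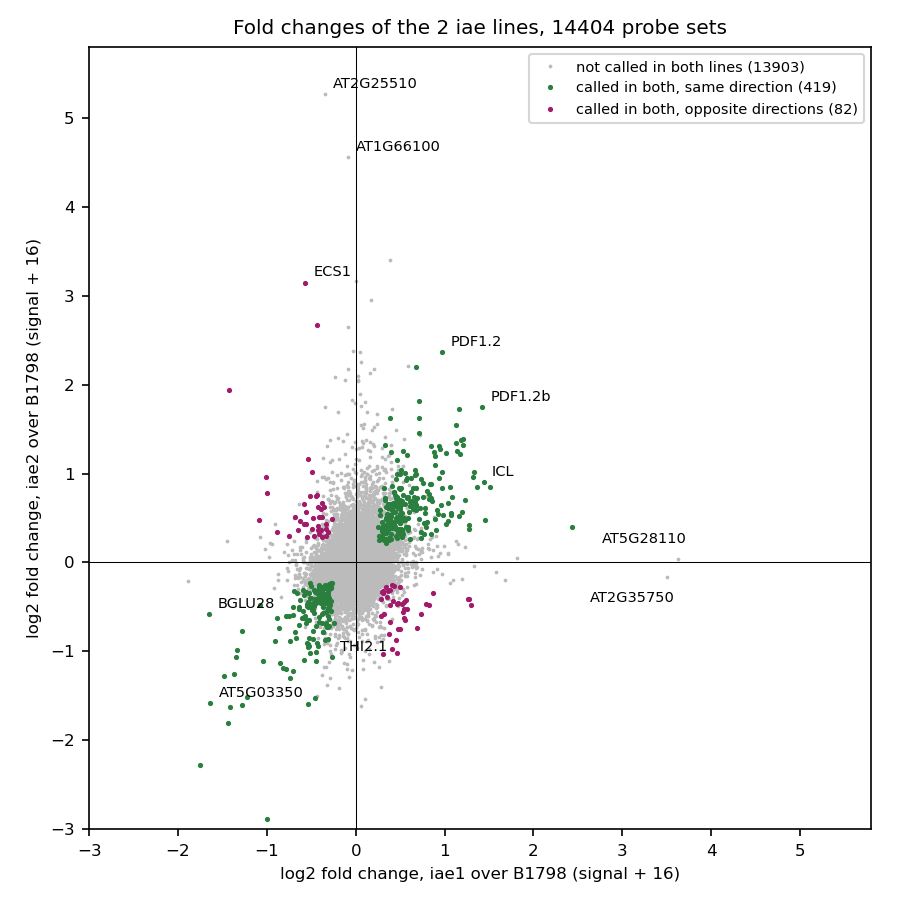
Log2 fold change over B1798 in iae1 (horizontal) and iae2 (vertical) of 14404 probe sets, on the log2(signal + 16) scale; colours mark the 419 called in both lines in the same direction and the 82 called in opposite directions. AT2G25510 and AT1G66100 lie far up the iae2 axis, and AT5G28110 and AT2G35750 far along the iae1 axis.

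Probe sets called in iae1 or iae2 alone were compared between the lines directly. Of 2057 called in iae2 and not in iae1, 1349 also differed between iae1 and iae2, and of 538 called in iae1 and not in iae2, 341 did. BGLU46, AT1G66100 and AT2G25510 belong to the former set, and AT2G35750, AT3G13610 and AT4G17470 to the latter. Over the whole design, the moderated F test called 3514 of 14404 probe sets (24.4%). In fits added later it called 1938 with the GAPDH ratio as a covariate and 2234 without iae1 replicate 3 and iae2 replicate 2.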

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

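The tests of a single chromosome segment, of the covariance against simulations and those with the GAPDH ratio or scanner background as covariate were chosen only after the result was seen. Probe sets that moved in opposite directions in iae1 and iae2 were singled out as a difference between the lines. There were 82 such probe sets, 41 higher in iae1 and 41 higher in iae2, and 39 had a single named gene. A call between the lines follows from that selection, so the contrast of iae1 with iae2 gives only sizes here. With the B1798 arrays divided between the contrasts, a choice made later, 28 to 49 probe sets were called in opposite directions, with fewer arrays in each. AT2G07140, AT1G13930, AT1G33055, AT5G58980 and AT1G12080 were outside the rule for named genes. They were picked among the 39 by the size of the smaller of their opposite changes. A probe set unnamed here moved further, with a log2 fold change of -1.43 in iae1 (adjusted p = 2.38e-06) and 1.94 in iae2 (adjusted p = 2.59e-08). Groups of 3 arrays were not tested for a sample far from the others.

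ECS1 differed by -3.71 (log2, iae1 minus iae2, adjusted p = 6.44e-12). AT2G07140, read by a probe set that can cross-hybridise, differed by 1.43 (adjusted p = 1.51e-06), with signals of 81.1 in iae1, 44.5 in B1798 and 19.9 in iae2. AT1G13930 differed by -1.26 (adjusted p = 7.59e-09) and COR15B by -1.20 (adjusted p = 3.02e-06). AT1G33055 differed by 1.2 (adjusted p = 2.17e-08), with 402 in iae1, 268 in B1798 and 166 in iae2. AT5G58980 differed by -1.12 (adjusted p = 3.49e-05), AT1G12080 by 1.09 (adjusted p = 3.16e-07) and BCAT4 by 1.06 (adjusted p = 1.14e-06). In iae1 against B1798 the COR15B call was lost without iae1 replicate 1 or 2 or B1798 replicate 2 or 3 (adjusted p up to 0.136), and the BCAT4 call without iae1 replicate 2 or 3 or B1798 replicate 2 or 3 (up to 0.0896).

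More probe sets were called in iae2 (2558) than in iae1 (1039, or 615 without B1798 replicate 2 and 650 without iae1 replicate 3). ECS1 and AT2G25510 were among the largest rises in iae2. With the GAPDH ratio as covariate the order of these counts turned, with 526 in iae2 and 645 in iae1. The median standard error of the main calls rose more in iae2 (0.0991 to 0.185) than in iae1 (0.096 to 0.109). Calls of at least 2-fold kept the order, with 222 in iae2 and 72 in iae1, against 183 and 67 without the covariate. A single introgressed segment that changes only its own genes was argued against as the sole source. The fullest run of 500 consecutive tested genes held 17.39% of the 92 genes called at 2-fold or more (16, on chromosome 5). An even spread gives 6.51% for a fixed run, and a fullest run lies above that by selection. The fullest runs held 15.2% in iae1 against B1798 and 16.1% between the iae lines. A segment that also changes genes elsewhere, several segments, and the iae2 line's own difference stay open and untested. Scanner background was argued against by a median ratio of fold changes with and without that covariate of 0.991 (quartiles 0.932 and 1.05). With the GAPDH 3'/5' ratio as covariate the median ratio was 1.00 for the 183 calls of at least 2-fold (quartiles 0.880 and 1.11, 148 still called). The GAPDH ratios of iae2 and B1798 did not overlap, so that fit rests on the spread within lines. It argues against RNA quality for these calls only if the GAPDH ratio acts within a line as it does between lines. Over all 2558 calls the median ratio of fold changes was 0.952, with quartiles of 0.664 and 1.22 and 481 still called. The standard error rose from a median of 0.0991 to 0.185, with the GAPDH ratio lying apart by line. For the small changes RNA quality and line therefore cannot be told apart.

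The calls shared by iae1 and iae2, such as AT5G03350 and PDF1.2b, could come from the B1798 arrays that both contrasts use. The covariance of the log2 fold changes was 0.0238, above the highest of 100 simulations with shared arrays and no effect (0.00765). The simulations drew each probe set independently with a spread pooled over the lines, so their range may be too narrow. With the B1798 arrays divided so that no array was shared, the covariance was 0.0122 to 0.0169. Together these values argue against the shared arrays alone. Without each B1798 array in turn, 297, 230 and 288 of the 419 shared calls were still called in both lines, the lowest without replicate 2, which argues against a single B1798 array as the source of all of them. A difference of B1798 itself from both iae lines stays open and was not tested.

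Other ways of grouping the arrays were counted beside these results. The 6 arrays of a contrast can be split in 10 ways, too few for a share under 0.05: the real split gave 1039, 2558 and 2825 calls for iae1 against B1798, iae2 against B1798 and iae1 against iae2, the highest other split gave 0 in each, and 1 split, the real one, was as large. For calls over any line, the real grouping gave 3514 and the highest other of 100 drawn from 280 gave 1639. For shared calls the numbers were 419 and 89 over 100 drawn from 840. Both argue against a chance division of the arrays, but technical replicates of a line would give the same outcome. The other divisions mix the lines and leave fewer calls to share. The 89 is therefore no measure of how far iae1 and iae2 share changes.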

How the results depend on the processing

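The fits with the GAPDH ratio or scanner background as covariate, without 2 arrays in doubt (iae1 replicate 3 and iae2 replicate 2) and without probe sets that can cross-hybridise were chosen only after the result was seen. Of 109 calls of named genes, 86 were still called with the GAPDH ratio, 103 with scanner background and 97 without the 2 arrays, and 0 of those with a value were lost without those probe sets. In the other 21 settings, 12 alternatives and 9 arrays left out, 93 passed wherever they had a value (the filter at the 60th percentile left out 10 of the 93), 16 were lost in at least 1 (SBPASE and THI2.1 in iae1 among them) and 0 reversed, and 12 values not called were called in some setting. At an adjusted p under 0.01 the calls were 443 for iae1 and 1443 for iae2 against B1798, 1576 between iae1 and iae2 and 1999 over any line, by construction fewer. Without the 2 arrays in doubt they were 572 for iae1, 1616 between the lines, 2234 over any line and 215 shared, with fewer arrays. With the GAPDH ratio they were 645, 526 and 1470 for the 3 contrasts, 1938 over any line and 122 shared, with larger standard errors. With the B1798 arrays divided between the contrasts, also chosen later, 110 to 184 were shared, with fewer arrays in each. With a single probe set per gene, 193 calls of the main fit were shared. The drop comes mainly from leaving out probe sets without a single located gene, since only 61 genes had several probe sets. Neighbouring lost genes rose to 9 pairs in iae1 and 53 in iae2 with no fold minimum, since 233 and 577 genes then entered (7.03 and 43.2 pairs expected). In iae2 they rose to 1 pair each with log2(value + 4) and with values below 16 set to 16 (permutation p = 0.176 and 0.201), and the cause was not tested. With quantile normalization 2 lists passed (jasmonate and heat shock in iae1); the cause was not tested. The variance alternatives do not enter camera and gave no value for the lists, and the fit of 2 lines none for the F test.

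Leaving out each array in turn gave 615 to 1026 calls for iae1, lowest without B1798 replicate 2 and 650 without iae1 replicate 3, and 248 to 399 shared calls, lowest without B1798 replicate 2 and 269 without iae1 replicate 3. It gave 1947 to 2519 calls for iae2, 2010 to 2933 between the iae lines and 2713 to 3467 over any line, 0 neighbouring pairs in both lines, and 0 to 1 lists, the 1 being glucosinolate in iae2 without B1798 replicate 3. A group left with 2 arrays was assumed to vary like the others. The replicate numbers did not pair the samples: same-number deviations correlated at -0.147 to 0.141, and 4 of 9 arrays correlated best with their own number. With the number as a block the calls were 982, 2499 and 2745 for the 3 contrasts, and THI2.1 in iae1, EIN3 in iae2 and DFR between the lines were not called. Scanner background as covariate gave 980, 2023 and 2445. Signals near the array background, with about 30.1% of values under 16 in iae2, limit what can be seen of dim genes such as COR15A and RALFL27.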

Other observations

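The gene sets, the neighbouring pairs of genes called higher, the test of a common shift of plastid RNA and the fit with the GAPDH ratio were chosen only after the result was seen, as were the genes in this section outside the rule for named genes. Sets were formed from genes that share a symbol stem, from plastid genes and from pseudogenes, 30 in all, and were tested with camera in the 3 contrasts. In iae1 against B1798, serine carboxypeptidase-like genes were lower: 6 of 14 passed, among them SCPL45 (log2 fold change -0.77, adjusted p = 0.00493) and scpl25 (-0.40, adjusted p = 0.0141), with a set adjusted p = 0.00254, or 0.174 with an estimated correlation. Glutathione S-transferase genes of the tau class were higher, 3 of 9, namely GSTU26 (0.80, adjusted p = 0.000495), GSTU22 (0.68, adjusted p = 0.00437) and GSTU23 (0.39), with a set adjusted p = 0.0405, or 0.276 with an estimated correlation. In iae2, 3 of 9 rose as well, GSTU16 from 154 ± 11.4 to 319 ± 7.45 (0.98), GSTU22 (0.59, adjusted p = 0.00463) and GSTU26 (0.46, adjusted p = 0.0115), with a set adjusted p = 0.0502, or 0.366 with an estimated correlation. Between the iae lines, 4 of 6 genes of xyloglucan endotransglucosylases, enzymes that remodel the cell wall, were higher in iae1, namely XTH18 (0.90), XTH19 (0.69), XTH16 (0.53) and XTH33 (0.35), with a set adjusted p = 0.0266, or 0.431 with an estimated correlation. The 25S rRNA signal was higher on every iae1 array than on every array of the other lines. The GAPDH 3'/5' ratio was lower on every iae2 array than on every iae1 and B1798 array, and with it as covariate 3 of the 6 XTH genes were called (set adjusted p = 0.0349, median log2 difference 0.44 before and 0.46 after). With it the tau class had 2 calls in iae1 (set adjusted p = 0.0497, median log2 fold change 0.39 before and 0.33 after) and 1 in iae2 (0.0491, 0.34 and 0.44), and the carboxypeptidase-like set 1 in iae1 (0.000498, -0.27 and -0.25). The stem PDF in iae1 (2 of 6 higher, PDF1.2 and PDF1.2b; set adjusted p = 0.00471, or 0.297 with an estimated correlation) mixes defensins with peptide deformylases, and the stem CYP (1 of 11 lower, CYP71B23; set adjusted p = 0.00471, or 0.18 with an estimated correlation) mixes cytochromes P450 with cyclophilins.

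Genes called higher by at least 2-fold in iae2 held 3 neighbouring pairs among 69 genes, with 0.611 expected (one-sided permutation p = 0.0225, or 0.135 adjusted over the 6 neighbour tests), so they did not pass. The pairs were AT2G25450, a dioxygenase gene of glucosinolate synthesis (log2 fold change 2.05), with AT2G25510 (5.27), the methyltransferase genes AT5G37990 (2.18) and AT5G38020 (1.36), and AT5G44400 (1.04) with PDF1.2 (2.37). In iae1 the 26 such genes held 0 pairs (permutation p = 1). The 82 genes higher in iae2 than in iae1 held 3 pairs (expected 0.864, permutation p = 0.0549), the first 2 of these and AT1G64360 with AT1G64370.

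The plastid transcripts ccsA (log2 fold change 1.69, adjusted p = 1.5e-09), psaA (1.21), ycf3 (0.84), psbK (0.71) and rpl33 (0.26) rose in iae2 against B1798, and petN (-1.03), atpH (-0.57) and psbA (-0.46) fell. Of 66 plastid transcripts tested 5 were called higher and 11 lower, with 6 and 10 under quantile normalization and 4 and 11 with equal array medians. A common shift of plastid RNA yield as the sole source was argued against by the smaller count, 5, since it would move all called members the same way. A shift together with changes of single transcripts stays open and was not tested. The median log2 fold change of the 66 was -0.11 in iae2. With the GAPDH 3'/5' ratio as covariate the median ratio of fold changes of the 16 calls was 1.02 with quartiles of 0.477 and 1.28 and 3 still called, the median standard error having risen from 0.104 to 0.183, so RNA quality and line cannot be told apart for these transcripts. A change of plastid transcripts in iae2 stays open as a hypothesis. The cDNA was primed with oligo-dT, so these signals read only RNA primed in that way and may not follow total plastid transcript levels.

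Between iae1 and iae2, 17 plastid transcripts were higher and 4 lower in iae1 (ccsA, psaA, rps18 and psbK), with a set adjusted p = 0.0325, or 0.582 with an estimated correlation. With the GAPDH ratio as covariate 12 were higher and 2 lower (set adjusted p = 0.0349, median log2 difference 0.17 before and after). Among probe sets unnamed here, the largest rise in iae1 was from 2.87 ± 1.5 in B1798 to 85.9 ± 5.55 (log2 fold change 2.43, adjusted p = 2.14e-08), and the largest in iae2 from 173 ± 16.4 to 1194 ± 188 (2.67, adjusted p = 1.54e-10). Another unnamed probe set fell in both lines, from 542 ± 29.7 to 150 ± 14.7 in iae1 (-1.75) and 98.9 ± 7.66 in iae2 (-2.28). Of 61 genes with several probe sets, 20 had a call in iae2 against B1798, 3 of them (AT1G51110, AT3G44510 and AT4G16180) with all probe sets called in the same direction, 0 with calls in opposite directions and 5 with a probe set of opposite sign to the call. In iae1 3 had a call, 0 of them in all probe sets. Between the iae lines 15 had a call, 3 of them with all probe sets called in the same direction and 3 with a probe set of opposite sign, among them AT1G23440 with calls in both directions (-0.56 and 0.45).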
